A study of Mus musculus with 2 samples.

How the data were processed

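Chromatin of mouse forebrain at postnatal day 0 was immunoprecipitated with an antibody to H3K27me3, the trimethylation of histone H3 laid down by Polycomb repressive complex 2, and the recovered DNA was sequenced (ChIP-seq). The labels name 1 group of 2 biological replicates. Each replicate was a pool of forebrains from male and female mice, 15 animals in replicate 1 and a number not given for replicate 2, and each had 2 technical replicates. Library fragments spanned 300 to 500 bp, per the labels. The labels call the samples biological replicates of one strain background, and the spread given here is the spread between these 2 pools.

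Each replicate came with the peak list the authors had called from it. A further pair of lists covered the whole series. One was called on both replicates pooled, and the other, the replicated list, was derived by the authors from the pooled list and both replicates' lists, per the deposited description of the files. Coordinates are on mm10, per the deposited descriptions and the labels. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. The signal value of each peak is the authors' own, a narrowPeak signal that was never under 1 and whose reference is not stated in the deposited files. The −log10 p and −log10 q of each peak are also the authors' deposited values, and the lowest −log10 p was 2.01 in replicate 1 and 2.05 in replicate 2. These per-peak values were used to describe, rank and filter peaks. The score and summit columns of the lists, 2 in number, were not used. Read numbers per library are not given in the sources used here, so the depth is unknown and no counting interval could be attached to a single peak.

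The reference was GRCm38.p6, the same build as mm10, with the GENCODE M21 annotation. No peak ran past the end of its chromosome (0 of all peaks). The 21938 protein-coding genes on the autosomes, X and Y formed the background, and each was represented by its outermost annotated 5′ end. All symbols of the fixed lists were found in the annotation (0 missing). Some annotated models in the Hox clusters are long read-through models, so that Hoxd3 and Hoxd4, or Hoxa3 and Gm28308, have nearly the same 5′ end.

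A peak of one replicate counted as found in the other when at least 50% of its length was covered. The observed overlap was set beside 100 circular shifts of replicate 2's peaks along each chromosome. Signal values were compared across replicated peaks that overlapped a peak in both replicates, taking the highest overlapping value on the log2 scale. A gene counted as carrying a peak when at least 1 bp of a peak lay within 2 kb of its 5′ end. The coverage of a gene is the share of the 10 kb around its 5′ end, 5 kb to each side, that lay in peaks. Coverage is given as mean ± SD over the lists of both replicates (n = 2). Replicated peaks were merged across gaps of up to 3 kb into domains, and those of at least 10 kb were called broad.

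Before the data were examined, 17 gene lists were fixed: 7 lists of developmental regulators (Hox genes, transcription factors of other brain regions, of cortex, of ventral telencephalon, of mesoderm and of endoderm, and signalling ligands), lists for neurons, astrocytes, oligodendrocytes, vessels, microglia and blood, and choroid plexus with ependyma and meninges, and lists of Polycomb, housekeeping, germline and olfactory receptor genes. The share of each list with a replicated peak was tested against all other protein-coding genes by 2-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 17 lists and a threshold of 0.05. Genes are not independent replicates, and neighbouring genes of a list can lie in one domain, so these p-values describe the annotation of 1 set of peaks and not the spread between animals. Each list was also compared with 10000 random lists of other genes drawn from the same 10 classes of CpG count within 500 bp of the 5′ end. Named genes were chosen by a rule fixed at the same time. It took from each list up to 4 members with the most replicated peak sequence near the 5′ end and up to 2 without a peak, then the genes in the 10 widest domains, the 10 genes outside the lists with the highest signal, and the 10 genes that differed most between replicates.

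The alternatives were an overlap of 1 bp or 80%, −log10 q of at least 2, −log10 p of at least 5, the top 20000 peaks of each list, windows of 500 bp and 5 kb, any annotated transcript start, gaps of 1 kb and 10 kb, all pooled peaks, autosomal genes, the CpG-matched lists, and each replicate left out in turn. Leaving out a replicate meant using the other replicate's own list. The interval arithmetic was checked against base-by-base counts (0 checks failed). The list test was tested on simulated data for 21938 genes in 50 simulations of the 17 lists. It called 0.118% of lists drawn at random, 22.5% of lists with 2 times the overall share and 97.4% of lists with 4 times that share. Each gene was marked independently there, so these rates do not carry over to lists of neighbouring genes, such as the Hox genes. When simulated peaks depended on CpG count alone, Fisher's exact test called 87 of 100 CpG-rich lists of 300 genes and the CpG-matched comparison called 2. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.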

Results

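H3K27me3 was mapped in forebrain of mice at postnatal day 0 in 2 biological replicates, each a pool of male and female animals. Replicate 1 gave 58321 peaks over 18.0 Mb and replicate 2 gave 44268 peaks over 15.9 Mb. The pooled list held 68722 peaks over 27.5 Mb. The replicated list, the authors' selection from it, held 19561 peaks over 15.0 Mb, or 0.568% of the known genome sequence. Replicated peaks had a median width of 516 bp, against 258 bp in the pooled list, 224 bp in replicate 1 and 256 bp in replicate 2. In the replicated list 93.1% of peaks had a −log10 q of at least 2, against 54.3% in the pooled list, 25.0% in replicate 1 and 47.5% in replicate 2. Replicated peaks carry the q of the pooled replicates, so the pooled list is the like comparison. There is no second group, so the comparisons below are between replicates, between gene lists and between regions.

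The widest stretches of H3K27me3 in newborn forebrain lay over the 4 Hox clusters, which encode the transcription factors that set position along the trunk and hindbrain. Peaks covered 83.8% ± 0.0927 (SD, n = 2) of the HoxA cluster (chromosome 6, 52155590 to 52260880) and 85.7% ± 1.17 (n = 2) of HoxC (chromosome 15, 102921103 to 103036852). Coverage was 80.6% ± 2.01 (n = 2) of HoxD (chromosome 2, 74668310 to 74765142) and 69.2% ± 0.816 (n = 2) of HoxB (chromosome 11, 96194316 to 96368256). In HoxB a stretch with few peaks separated Hoxb13, which had its own domain of 58.3 kb, from the domain over Hoxb9 to Hoxb1. In the replicated list the covered shares were 96.0% of HoxA, 78.8% of HoxB, 96.1% of HoxC and 91.3% of HoxD. Hoxa4, Hoxb5, Hoxb3 and Hoxb4 were named by the sequence of the replicated list within 5 kb of their 5′ ends. The replicates' own lists covered 93.2% ± 2.41, 89.2% ± 3.31, 87.2% ± 0.410 and 86.8% ± 5.55 (SD, n = 2) of these 10 kb windows, and the windows of some other Hox genes to a similar extent, such as Hoxc12 with a mean of 90.4% ± 1.75 (singled out after its value was seen).

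**Figure D1:**
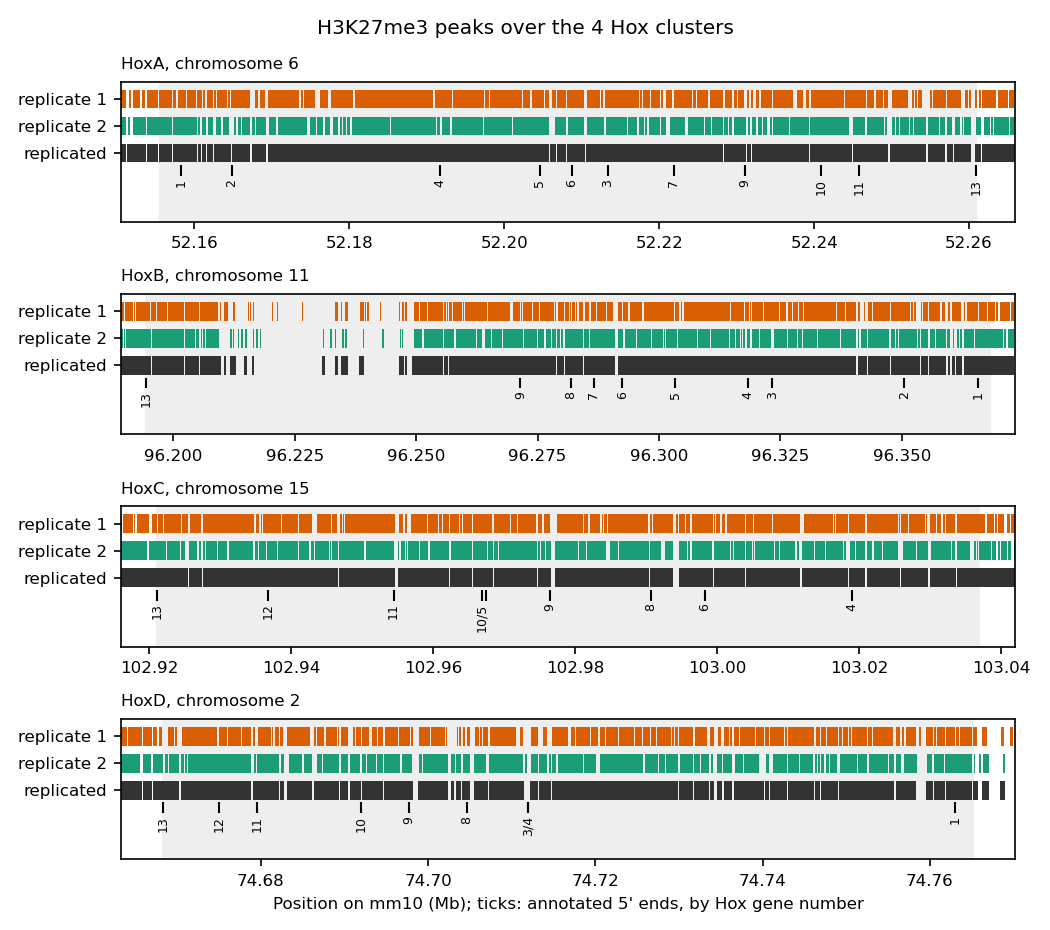
Peaks of replicate 1 (orange), replicate 2 (green) and the replicated list (black) over the 4 Hox clusters, against position on mm10 in Mb, with ticks at annotated 5′ ends. Grey shading marks each cluster from the start of its first to the end of its last Hox gene, and the mean coverage of HoxB (69.2%) is below that of the other clusters, with few peaks in the stretch next to Hoxb13.

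Merging replicated peaks across gaps of up to 3 kb gave 7541 domains, of which 487 were at least 10 kb wide and held 45.5% of the domain length. After the domains of HoxA (183.3 kb), HoxC (182.5 kb), HoxB (133.0 kb) and HoxD (126.8 kb) came Nkx2-1, a regulator of the medial ganglionic eminence and thyroid, with 104.6 kb (chromosome 12, 56440159 to 56544761). Pax3, a regulator of dorsal neural tube and neural crest, lay in a domain of 88.6 kb (chromosome 1, 78133125 to 78221758), and the neighbours Zic1 and Zic4 in one of 75.2 kb (chromosome 9, 91347543 to 91422711). A domain of 64.4 kb overlapped Ebf3 and held no outermost 5′ end of a protein-coding gene (chromosome 7, 137181554 to 137245953). The 5′ ends of Ebf1 and of Tbx5, a heart and forelimb regulator, lay in domains of 62.8 and 61.1 kb. The replicates' own peaks covered 57.7% ± 5.16 (SD, n = 2) of the domain at Nkx2-1, 75.4% ± 0.369 of that at Pax3 and 59.4% ± 3.36 of that at Tbx5. They covered less of the domains at Ebf3 (43.1% ± 4.54) and Ebf1 (42.2% ± 8.75). The number of broad domains depends on the merging: gaps of up to 1 kb gave 271 and gaps of up to 10 kb gave 886. Merged in the same way, replicate 1's own list gave 714 broad domains and replicate 2's gave 597.

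Across the genome, 2610 of 21938 protein-coding genes (11.9%) had a replicated peak within 2 kb of the 5′ end. The replicates' own lists marked 3787 and 3458 genes, a mean of 3622.5 ± 232.6 (SD, n = 2), and 2652 genes were marked in both. The pooled list marked 4385 genes, more than 1.5 times the replicated count. Windows of 2 kb around 5′ ends held 26.6% of replicated peak sequence (18.5% in replicate 1 and 21.5% in replicate 2) while making up 3.07% of the genome. Other gene body held 33.8% of replicated peak sequence and 37.6% of the genome, and sequence outside genes held 39.6% and 59.3%.

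All 39 Hox genes and all 42 transcription factors of midbrain, hindbrain and spinal cord had a replicated peak, in both replicates as well, against 11.7% of other genes. Their adjusted p-values by Fisher's exact test were 3.86e-36 and 9.36e-39. In the midbrain, hindbrain and spinal cord list coverage was 85.3% ± 2.43 (SD, n = 2) at Nkx2-2, a ventral neural tube factor, 82.7% ± 0.396 at Mnx1, a motor neuron factor, 76.9% ± 4.06 at Foxa2, a floor plate and endoderm factor, and 74.7% ± 11.9 at Dbx1, an interneuron progenitor factor. Of the mesoderm, muscle and heart factors 40 of 46 were marked (adjusted p = 1.53e-30, Fisher's exact test), with coverage of 82.3% ± 2.76 at Pax9, 78.4% ± 1.92 at T, 73.1% ± 1.05 at Hand2 and 72.7% ± 8.42 at Tbx20. Meox1 and Mesp2 had no replicated peak within 2 kb of the 5′ end. Endoderm and gut factors were marked in 19 of 24 cases (adjusted p = 1.46e-13, Fisher's exact test), among them Foxl1 (83.4% ± 6.65), Pdx1 (81.2% ± 0.198) and Cdx2 (80.3% ± 0.106), while Hnf1a and Hnf4a, factors of liver and gut, were not marked. Developmental signalling ligands were marked in 36 of 46 cases (adjusted p = 1.73e-24, Fisher's exact test), among them Wnt10b (76.7% ± 11.5), Ihh (73.1% ± 5.95), Wnt10a (63.2% ± 2.57) and Wnt6 (61.4% ± 1.13). Bmp3 and Bmp5 were not. Hox genes of one cluster share a domain, so the marked genes of that list are not separate observations.

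Of the ventral telencephalic factors 19 of 22 had a replicated peak (86.4%; adjusted p = 7.82e-15, Fisher's exact test). Coverage was 71.4% ± 2.46 (SD, n = 2) at Six3, 66.8% ± 2.89 at Nkx2-1, 64.3% ± 4.86 at Lhx8 and 63.4% ± 1.32 at Gsx2. Ascl1 (3.05% ± 1.49), a proneural factor, and Foxp2 (3.35% ± 1.32) had no replicated peak within 2 kb of the 5′ end. Of the cortical glutamatergic factors 14 of 30 were marked (46.7%; adjusted p = 5.28e-06, Fisher's exact test), with coverage of 54.0% ± 5.51 at Eomes, a marker of intermediate progenitors, 51.6% ± 1.58 at Pax6, a radial glia factor, 49.0% ± 4.21 at Satb2 and 36.7% ± 6.46 at Fezf2, factors of upper and deep layer projection neurons. Bcl11a (0% ± 0) and Bcl11b (1.01% ± 1.44), factors of cortical projection neurons, had no replicated peak. The same list was marked at 51.7% ± 7.07 (SD, n = 2) over the replicates' own lists.

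**Figure D2:**
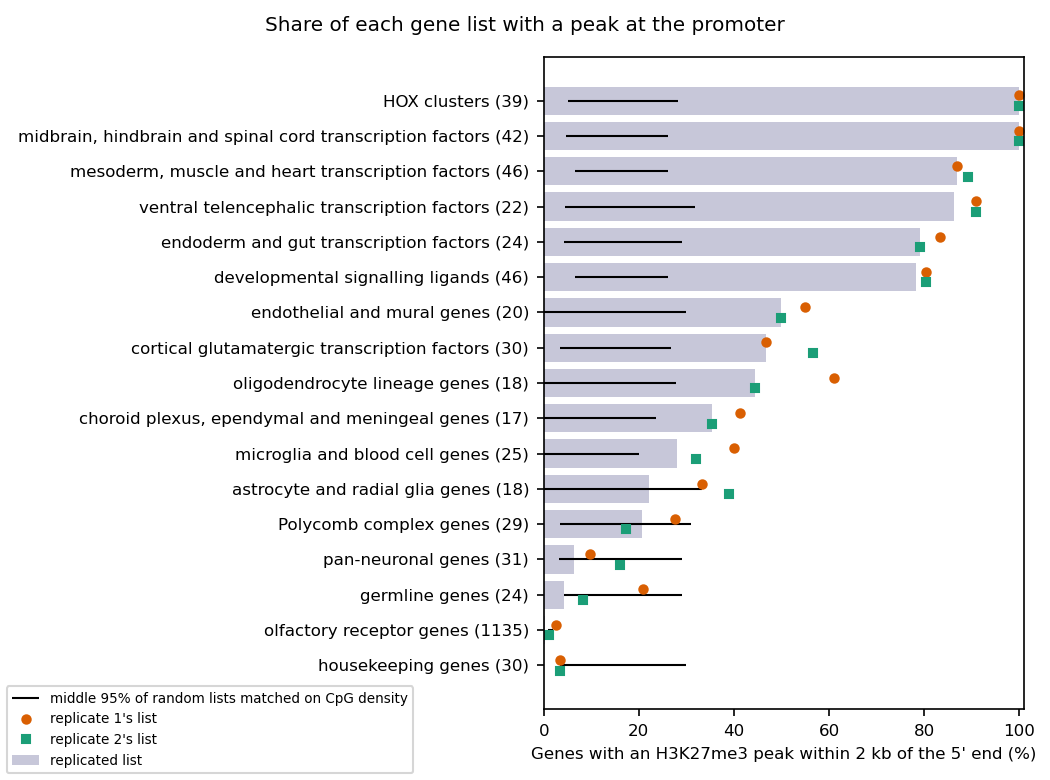
Percent of genes of each fixed list (number of genes in brackets) with a peak within 2 kb of the 5′ end in the replicated list (bars), replicate 1 (circles) and replicate 2 (squares). Black lines span the middle 95% of 10000 random lists matched on CpG density, and 6 of the 7 developmental lists have shares of 78.3% or more, the cortical list being at 46.7%.

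Among the markers of cell types, those of oligodendrocytes and vessels were marked more often than other genes and those of neurons did not pass the test. Of the oligodendrocyte lineage genes 8 of 18 had a replicated peak (adjusted p = 0.000978, Fisher's exact test), and over the replicates' lists the share was 52.8% ± 11.8 (SD, n = 2). The marked members included the lineage regulators Olig1 (69.8% ± 4.48), Pdgfra (59.5% ± 5.01), Olig2 (47.2% ± 7.0) and Sox10 (28.2% ± 7.90), while Cnp (6.84% ± 1.54) and Enpp6 (0% ± 0) had no replicated peak within 2 kb of the 5′ end. Endothelial and mural genes were marked in 10 of 20 cases (adjusted p = 6.28e-05, Fisher's exact test; 52.5% ± 3.54 over the replicates' lists), among them the vascular growth factor receptors Flt1 (50.6% ± 2.20) and Kdr (44.4% ± 0.707), Sox18 (49.4% ± 3.95) and Kcnj8 (43.7% ± 8.08). Acta2 and Cdh5 were at 0% ± 0. Of the pan-neuronal genes only the neurofilament genes Nefl (28.6% ± 0.573) and Nefm (6.44% ± 6.29) were marked in the replicated list, 2 of 31 (adjusted p = 0.575, Fisher's exact test), and these are neighbours on chromosome 14. The share was 9.68% in replicate 1's list and 16.1% in replicate 2's, and without replicate 1 the difference from other genes reversed, to 0.367 percentage points. Of the astrocyte and radial glia genes 4 of 18 were marked (adjusted p = 0.295, Fisher's exact test; 36.1% ± 3.93 over the replicates' lists), with 11.9% ± 5.47 at Gja1 and 6.26% ± 0.834 at Nes. Without replicate 1 that list passed the threshold (adjusted p = 0.0237, Fisher's exact test).

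Microglia and blood genes were marked in 7 of 25 cases (adjusted p = 0.0328, Fisher's exact test; 36% ± 5.66 over the replicates' lists, SD, n = 2). The marked genes included the blood cell regulators Tal1 (70.6% ± 1.88) and Gfi1 (60.8% ± 5.22) and the complement genes C1qc (20.99% ± 1.29) and C1qa (18.0% ± 5.13). Choroid plexus, ependymal and meningeal genes were marked in 6 of 17 cases (adjusted p = 0.0168, Fisher's exact test; 38.2% ± 4.16 over the replicates' lists), with 59.8% ± 7.03 at Otx2, 54.1% ± 0.983 at Foxc1, 32.6% ± 9.49 at the collagen gene Col1a1 and 17.5% ± 2.21 at Kl. Neither list passed the threshold without replicate 1 (adjusted p = 0.0614 and 0.0561, Fisher's exact test), and the microglia list also missed it with windows of 500 bp (adjusted p = 0.0660) and with any transcript start (adjusted p = 0.0853).

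None of 30 housekeeping genes had a replicated peak within 2 kb of the 5′ end (3.33% ± 0 over the replicates' lists, SD, n = 2), with coverage of 0% ± 0 at Actb and Chmp2a and 5.28% ± 3.90 at Rab7. The difference from other genes had an adjusted p of 0.0566 by Fisher's exact test and of 0.0149 against CpG-matched lists. Of 1135 olfactory receptor genes 3 were marked (0.264%, against 12.5% of other genes; adjusted p = 1.2e-57, Fisher's exact test), and the share was 2.56% in replicate 1's list and 1.15% in replicate 2's (1.85% ± 0.997, SD, n = 2). CpG-matched random lists had a mean of 1.48% with a replicated peak, a difference of −1.21 percentage points (adjusted p = 0.000378, permutation test by random lists). The marked genes were Olfr94 (18.3% ± 2.62), and Olfr12 and Olfr95, which are named here after their values were seen. Of the germline genes only the egg coat gene Zp2 (4.68% ± 1.27) was marked, 1 of 24 (adjusted p = 0.374, Fisher's exact test), while the share was 20.8% in replicate 1's list and 8.33% in replicate 2's. Without replicate 2 the difference from other genes reversed, to 3.57 percentage points. Of the genes for Polycomb complexes 6 of 29 were marked (adjusted p = 0.180, Fisher's exact test; 22.4% ± 7.31 over the replicates' lists), with coverage of 58.8% ± 11.4 at Cbx8, 22.0% ± 0.346 at Cbx4, 19.8% ± 3.92 at Pcgf1 and 11.2% ± 5.06 at Phf19. The subunit gene Bmi1 (10.3% ± 0.742) and the cofactor gene Aebp2 (0% ± 0) had no replicated peak within 2 kb of the 5′ end, though replicated peaks covered 11.6% of the 10 kb around that of Bmi1.

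Outside the fixed lists the promoters with the highest peak signal included further developmental genes and a tumour suppressor. The signal was 8.69 at Foxd2, 8.33 at Cyp26a1, which encodes an enzyme that degrades retinoic acid, and 7.97 at Cdkn2a, a cell cycle inhibitor that shares a domain of 49.6 kb with Cdkn2b (chromosome 4, 89265468 to 89315040). It was 7.79 at Tfap2a, Vgll2, Gjb2 and Insl3 and 7.61 at Dmrt2. Coverage at these genes was 76.0% ± 4.43 (SD, n = 2) for Foxd2, 82.2% ± 2.18 for Cyp26a1, 75.1% ± 11.3 for Cdkn2a and 76.1% ± 0.587 for Tfap2a. 5730596B20Rik (9.60) lies inside the HoxA domain and 9230102O04Rik had a signal of 7.61.

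The replicates shared most of the peaks of lowest p and fewer of the rest. In the 10% of each list with the lowest p, 73.5% of replicate 1's peaks lay in replicate 2's list and 79.2% of replicate 2's lay in replicate 1's. In the next 10% these shares were already down to 43.2% and 49.6%, and in the 10% with the highest p they were 10.4% and 14.0%. Over all peaks, 14527 of 58321 peaks of replicate 1 (24.9%) were found in replicate 2 and 13218 of 44268 (29.9%) in the reverse direction, and the Jaccard index of covered sequence was 23.5%. After random shifts the means were 0.651%, 0.719% and 0.362%, with no shift above 0.878%, 1.01% and 0.546%. Limiting both lists to −log10 q of at least 2 left 14598 peaks in replicate 1 and 21039 in replicate 2. The share of replicate 1's peaks found then rose from 24.9% to 43.6%, while that of replicate 2's went from 29.9% to 28.8%. The limit also shortened the list searched, more so for replicate 1's list, so the latter share does not show how well replicate 2's stronger peaks were shared. At an overlap of 80% the shares were 15.1% and 16.4%.

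**Figure D3:**
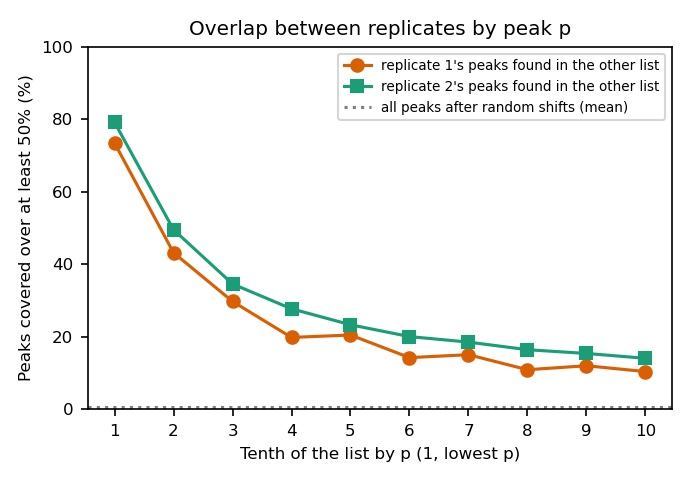
Percent of each replicate's peaks covered over at least 50% of their length by the other replicate's peaks, in 10 equal parts of the list from lowest p (1) to highest p (10). Circles show replicate 1 (73.5% to 10.4%), squares show replicate 2 (79.2% to 14.0%), and the dotted line shows the mean over all peaks after random shifts.

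Of the pooled peaks 28.5% were in the replicated list, with 54.7% of the pooled sequence. With −log10 q of at least 2 the share was 48.8%. Replicated peaks had a median signal of 3.50 and the other pooled peaks 2.72, with median widths of 516 and 226 bp. Of the replicated peaks 69.1% were found in replicate 1, 70.0% in replicate 2 and 46.0% (8994 peaks) in both at 50% overlap. The share of all pooled peaks found in both replicates was 13.1%, 21.1% with 1 bp of overlap and 2.26% with 80%. At 50% overlap all such pooled peaks were in the replicated list, so 13.1% and 46.0% count the same 8994 peaks. At 1 bp of overlap 5415 replicated peaks (27.7%) had no peak in at least 1 replicate's list, 2803 with one in replicate 1 alone, 2324 in replicate 2 alone and 288 in neither. Across the 14146 replicated peaks with a peak in both replicates the log2 signals had a Spearman's rho of 0.459 and a Pearson's r of 0.509. These describe peaks within a pair of lists, and peaks are not independent replicates. A wide replicated peak can take the highest of several values in each list, and width was not adjusted for.

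Among the chromosomes, the X was the one on which the replicates' peak numbers parted. Replicate 1 had 2900 peaks on the X (4.97% of its list) and replicate 2 had 248 (0.560%), a ratio of 11.7, while on the 19 autosomes the ratio ran from 1.22 to 1.31. Per Mb of known sequence replicate 1 had 17.7 peaks on the X, inside its range over the autosomes (13.8 to 37.5), and replicate 2 had 1.52, below its range (10.7 to 30.7). Of replicate 1's 2900 X peaks 363 had a −log10 q of at least 2, as did 99 of replicate 2's 248. Windows of 2 kb around 5′ ends held 7.11% of replicate 1's X peak sequence, against 18.9% on its autosomes and 22.6% on the X in replicate 2. These windows make up 2.12% of the X and 3.14% of the autosomes. The replicated list had 218 peaks on the X, 1.33 per Mb against 4.12 to 14.4 on the autosomes, and no list had a peak on the Y. Of the 10 genes that differed most between replicates, Cdx4 (40.5% in replicate 1 and 14.4% in replicate 2) and Chic1 (22.2% and 0%) are neighbours on the X. Across the 74.7 kb from Cdx4 to the end of Chic1 (chromosome X, 103321398 to 103396092) 38 peaks of replicate 1 covered 15.0% and 7 peaks of replicate 2 covered 2.58%. The others of these 10 are autosomal: coverage was higher in replicate 1 at Lmo3 and Stpg2 and higher in replicate 2 at Pitx2 (56.3% in replicate 1 and 82.8% in replicate 2), Ush1g, Alx4, Cebpa, Dmrt2 and Bnc1.

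**Figure D4:**
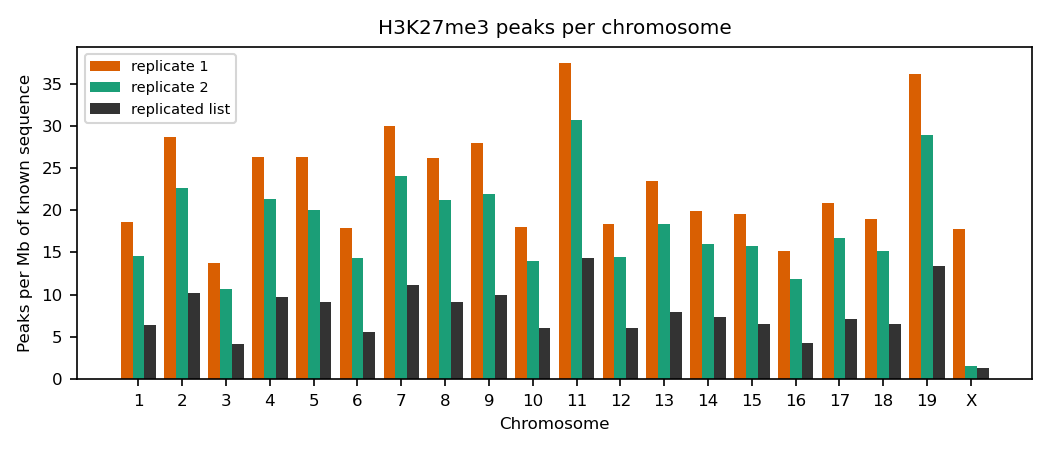
Peaks per Mb of known sequence on each chromosome in replicate 1 (orange), replicate 2 (green) and the replicated list (black). On the X replicate 1 has 17.7 peaks per Mb and replicate 2 has 1.52, whereas on each autosome replicate 1 has 1.22 to 1.31 times the peaks of replicate 2.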

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

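All alternatives were fixed in advance except 3 chosen after seeing the data: overlap on autosomes only, replicated peaks with a peak in both replicates, and Hox coverage in the replicated list. The cause of the changes below was not tested unless the construction of the alternative gives it. Over the 17 gene lists, 156 of 170 comparisons kept their direction and their side of the threshold, 5 lost the call, 6 gained it and 3 reversed. The 7 developmental lists, the oligodendrocyte and endothelial lists and the olfactory receptors kept both under every alternative run.

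The share of replicate 1's peaks found in replicate 2 moved to 33.1% with 1 bp, 15.1% with 80%, 43.6% with −log10 q of at least 2, 43.1% with −log10 p of at least 5, 36.1% in the top 20000 peaks and 26.1% on autosomes. For replicate 2's peaks the values were 41.4%, 16.4%, 28.8%, 29.2% and 33.3% under the first 5 of these. Limits on q, p and rank were set on both lists, so they also shortened the list searched. The Jaccard index was 30.1% at −log10 q of at least 2, 30.2% at −log10 p of at least 5, 30.1% in the top 20000 and 24.0% on autosomes. Spearman's rho was 0.474 with −log10 p in place of the signal and 0.426 at −log10 q of at least 2. The replicated share of pooled peaks was 48.8% at −log10 q of at least 2, and the share found in both replicates was 21.1% with 1 bp and 2.26% with 80%. All pooled peaks marked 4385 genes. Broad domains numbered 271 with gaps of 1 kb and 886 with gaps of 10 kb.

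At −log10 q of at least 2 coverage was 79.7% of HoxA, 65.6% of HoxB, 82.3% of HoxC and 75.0% of HoxD. With gaps of up to 3 kb filled it was 100%, 88.0%, 100% and 100%, and in the replicated list 96.0%, 78.8%, 96.1% and 91.3%. The replicate SDs there are small, so that any change counts. Peak sequence near a 5′ end was 18.5% to 21.5% with a replicate left out.

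As list share minus that of other genes in percentage points, by Fisher's exact test, the astrocyte list gained the call with windows of 5 kb (18.9, adjusted p = 0.0464) and with all pooled peaks (35.6, 0.00139), and ran from 16.1 to 23.1 with a replicate left out. The microglia and blood list lost it with windows of 500 bp (11.9, 0.0660), any transcript start (14.4, 0.0853) and peaks in both replicates (13.8, 0.0525), and ran from 16.3 to 22.8 with a replicate left out. The choroid plexus list ran from 19.5 to 23.9. The housekeeping list gained it with any transcript start (−13.6, 0.0393) and all pooled peaks (−16.7, 0.0242), and also against CpG-matched lists, where the difference is from their mean and the test a permutation test by random lists (−15.8, adjusted p = 0.0149). Lists not called either way reversed: Polycomb genes with windows of 500 bp (−4.63), pan-neuronal genes (−7.60 to 0.367) and germline genes (−7.44 to 3.57) with a replicate left out. Depth is unknown and could not be weighed.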

Other observations

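The gene families below were chosen only after the fixed lists had been seen, as were the comparison of the cortical list with others, the test of the X chromosome by q, its ratios outside the fullest bins and the test of the peaks of lowest p. Leaving out every gene of the fixed lists, 20 families taken by symbol were compared with all other genes by Fisher's exact test, adjusted over the 20. Of these, 13 were marked more often and 3 less often, and 14 of the 16 also passed against CpG-matched lists, the exceptions being T-box genes and ephrins with their receptors. All 6 Iroquois genes (Irx1 to Irx6) had a replicated peak (adjusted p = 6.95e-06, Fisher's exact test), as did all 4 remaining NK homeobox genes (0.000406) and 15 of 32 forkhead genes (2.44e-06; 48.4% ± 2.21 over the replicates' lists, SD, n = 2). Also marked more often were 39 of 92 potassium channel genes (6.89e-13, with 49.5% ± 3.84 over the replicates' lists, SD, n = 2) and 13 of 23 serotonin and adrenergic receptor genes (1.24e-06, with 73.9% ± 6.15). Of 17 genes with symbols of ionotropic glutamate receptors 11 were marked (adjusted p = 1.28e-06, Fisher's exact test, with 61.8% ± 4.16), among them Grin2a, Grin2c and Grik4. These 11 include Grid2ip, which was caught by its symbol and is not a receptor subunit gene. Gria2 and Grin2b, members of the pan-neuronal list without a replicated peak at the promoter, were left out. GABA-A receptor genes (2 of 18, adjusted p = 1; 13.9% ± 3.93 over the replicates' lists, SD, n = 2), nicotinic receptor genes (3 of 16, 0.495; 34.4% ± 13.3), semaphorin genes (2 of 20, 1; 20% ± 0) and keratin genes (5 of 53, 0.922; 16.0% ± 4.00) did not pass Fisher's exact test. The replicates' own lists marked 43.75% and 25% of the nicotinic receptor genes, against 18.75% in the replicated list. Zinc finger genes named Zfp were marked less often, 12 of 394 (5.78e-09; 6.73% ± 0.179), and none of the 57 clustered protocadherin genes (0.00260; 0.877% ± 1.24) or 331 vomeronasal receptor genes (5.54e-17; 0.604% ± 0) was marked. For the vomeronasal receptors most of the difference went with CpG density, since matched lists had a mean share of 1.27% (permutation test by random lists, adjusted p = 0.0369), against 13.5% for the protocadherins (0.000571). Neighbouring members of a family, as in the Irx clusters, can share a domain, and genes are not independent replicates.

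Among brain regulators, the 14 of 30 cortical factors with a replicated peak were fewer than the 19 of 22 ventral telencephalic factors (difference −39.7 percentage points, adjusted p = 0.00398) and the 42 of 42 midbrain, hindbrain and spinal cord factors (−53.3, adjusted p = 7.07e-08) by 2-sided Fisher's exact test. The differences were −44.2 and −53.3 in replicate 1's list and −34.2 and −43.3 in replicate 2's.

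The share of X peaks in replicate 1's list was 8.88 times that in replicate 2's (95% interval 7.80 to 10.1). It fell to 5.28 (4.24 to 6.59) at −log10 q of at least 2, which 363 of 2900 X peaks of replicate 1 and 99 of 248 of replicate 2 passed. For this pair of lists, weak calls near a threshold are argued against as the whole cause but not as a part of it. The intervals given here treat each peak as an independent draw. Peaks cluster, so the intervals are too narrow, and with 1 pool on each side they do not measure the spread between pools. One or a few aberrant stretches are argued against as the whole cause: the 2 fullest 10 Mb bins of replicate 1 held 42.6% of its X peaks, under the 50% predicted, and outside them the ratio of peak numbers was 10.2 (8.65 to 11.9), against at most 1.31 on the autosomes. The peaks were uneven (1 to 654 per bin that held any), and 6 bins held 87.2% of replicate 1's and 76.2% of replicate 2's, with a ratio of 6.27 (4.76 to 8.25) outside them, so a part for stretches within those bins stays open. A different amount of X material relative to the control, higher in replicate 1 or lower in replicate 2, cannot be told apart from no such difference. At 84 X peaks in both lists the median log2 signal ratio lay 0.0093 above that at 14440 autosomal ones. Its bootstrap interval of −0.06 to 0.16 holds both 0 and the 0.1 looked for. Only peaks called in both lists entered, so the X peaks called in replicate 1 alone were left out and the test cannot decide for them. H3K27me3 coats the inactive X of females and both pools were of mixed sex, so the shares of males and females may have differed, which the labels do not give and which was not tested.

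Promoter CpG density, a known correlate of Polycomb binding, could be the source of the difference between gene lists. It is argued against as the whole cause, since 7 of the 7 developmental lists lay above the middle 95% of random lists matched on CpG density (permutation test by random lists, adjusted p = 0.000378 each, from the smallest p of 0.0002 that they can give). Some of these lists share members, such as Foxa1, Foxa2, Gata4, Gata5, Gata6, Satb2 and Gbx1, so they are not fully separate observations. CpG was counted within 500 bp of the outermost 5′ end and peaks within 2 kb, so CpG-rich sequence farther out was not matched. For olfactory receptors most of the difference went with CpG density: matched random lists had a mean share of 1.48%, against 12.5% for all other genes. A remainder of −1.21 percentage points was outside the middle 95% of matched lists (0.881% to 2.03%).

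Most signal values fell on evenly spaced levels, 65.3% of them at a spacing of 0.321 in replicate 1, 53.7% at 0.294 in replicate 2 and 61.5% at 0.181 in the pooled list, within 5e-05 of a level or in proportion for values above the most common one. A candidate explanation is that the value is the number of reads covering the summit of a peak plus 1, divided by a mean background plus 1. The spacing of replicate 2 predicted in this way from the other lists differed from the observed one by −0.0799%. If so, the background term was 1.14 times as large in replicate 2 as in replicate 1. Divided by the narrowest peak width of each list (200 bp in replicate 2 and 180 bp in replicate 1), it was 1.02 times as large. The depth of the libraries stays unknown.

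Of the 4 replicated peaks of lowest p, 2 overlapped Rn18s-rs5, a pseudogene of the multi-copy ribosomal RNA genes (chromosome 17, 39843005 to 39846789 and 39847855 to 39848920), with signals of 2.78 and 2.53, while the lowest p of all was at a peak within Cdk8 (chromosome 5, 146261003 to 146261482) with a signal of 7.23. The remaining peak (chromosome 11, 109011584 to 109012080) also had a low signal, 2.70, and overlapped the long noncoding RNA gene Gm36876 but no such pseudogene.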
